A study of Drosophila melanogaster with 24 samples.

How the data were processed

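Gene expression was measured in adult Drosophila melanogaster with a one-colour NimbleGen array labelled with Cy3. The array was designed for 16637 transcripts of FlyBase with 8 probes per transcript, per the labels. Flies of the lol (Lobe-less) mutant strain and of w1118, the control strain, were reared at 23 °C and frozen on day 2 of adult life, per the labels' protocols. Males and females were sorted, and total RNA came from whole bodies or from heads that were separated from frozen carcasses with a sieve. Each extraction used 100 bodies or heads. The 24 arrays fall into 8 groups (genotype by sex by tissue) of 3 arrays, and the labels describe the 3 as separate cultures.

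The authors deposited log2 expression values per transcript that had been made with RMA (robust multi-array average, which corrects the background, quantile normalizes probes between arrays and summarises the probes of a transcript), per the submitters' processing notes. The software version, and which arrays were normalized together, are not given in the sources used here. Base 2 was read from the values, which lay between 6.6134 and 15.9201, just under the 16 bits of a scanner. Of 15595 transcripts in the table, 1722 had no value on any array and were left out, which left 13873. The median of an array lay between 12.1 and 12.25. For arrays there is no count depth, and the number of arrays limits the precision. Transcripts with a mean over 15 (703 in all) lie close to the top of the scale, where differences are compressed.

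Transcripts carry FlyBase transcript IDs, and the files do not pair them with gene names. The reference table of Drosophila genes (Release 6) lists 49 such IDs among its synonyms. Of these, 44 are in the table and 43 were measured. A single gene was listed for 16 of the measured IDs, which are named here, and several genes for the other 27, which are not named. The remaining transcripts are given by ID, at most 2 that rose and 2 that fell per comparison. None of the 25 gene lists fixed before the data were examined (brain, sensory, immune, stress, metabolic, reproductive and tissue marker lists) reached its minimum of 5 members, since none of their members could be matched. The list tests and the tissue marker checks were therefore not run. The transcripts of lol, w, roX1, roX2, Yp1 and ninaE are not analysed here, so the mutated gene itself gives no check of the genotype labels.

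All comparisons came from 1 limma model (version 3.58.1, in R 4.3.3) with a mean for each of the 8 groups, fitted to all 24 arrays (lmFit, contrasts and eBayes with a constant prior). P-values were adjusted with the Benjamini-Hochberg method over the 13873 transcripts within a comparison, and adjusted values under 0.05 were called. A second count also required a log2 difference of at least 1. The comparisons were lol against w1118 in each sex and tissue, the difference of these effects between sexes and between tissues, and, within w1118, females against males and heads against whole bodies. Transcripts called in the same direction in all 4 genotype comparisons were counted beside the number that independent lists would give. The 4 genotype comparisons share no arrays, but they share the strains and the spread that the fit estimates per transcript. Errors are SDs over 3 arrays or SEs from the model.

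The rule for named genes, the comparisons, the lists and most alternatives were fixed before the data were examined. Per genotype comparison the rule took the largest differences among called transcripts of at least 1 log2 with every lol array on one side of every w1118 array. For the transcripts changed in all 4 comparisons it ranked by the smallest difference of the 4. In the remaining comparisons it took the most positive and most negative called ones. The limit of 2 IDs per direction shortened these lists, and the 16 named transcripts are reported together as a group.

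A total of 6 transcript sets stood in for tissue markers. They were defined from w1118 after the values had been seen, at an adjusted p under 0.05 and a log2 difference of at least 2. They were male-body-biased (1439 transcripts higher in male than female bodies), female-body-biased (180), head-enriched in females (280) and in males (493), body-enriched in females (586), and the 214 of these that differed by under 0.5 between the sexes in bodies (body-enriched, sex-neutral). Sets were tested with limma's camera at its preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the 6 sets. Where a set was defined on arrays that a comparison also uses, its shift there is partly built in.

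Alternatives were an intensity trend with a robust prior, fits to the arrays of one tissue or sex or to the compared groups alone, quantile normalization again, median centring, dropping the lowest 25% of transcripts by mean, array weights (whose fit stopped before it converged), the replicate number as a block, and leaving out each array in turn. A fit without 4 head arrays was chosen after the data had been seen. A fit with a single transcript per gene needs gene names and was not run. Replicate numbers come from the labels, which tie them to no shared day or batch. Deviations of same-numbered arrays from their group means correlated at 0.23, 0.29 and 0.34 in male whole bodies, so the numbers were taken to pair the arrays there, and not in the other comparisons. The block gave each replicate number a common effect across all 24 arrays, so it did not pair the male bodies alone. All values come from the fit without the block. The blocked value stands beside a result only where it moves a total count by over 1.5 times or changes a call. No pair of arrays shared more than 0.036% of equal values, so all 24 were kept as separate samples.

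The scripts were tested on simulated data with 200 of 13873 transcripts changed. For the genotype effect in female head, 10% of changes of 0.5 log2 were recovered, 62% at 1, 94% at 2 and 98% at 3, with 2 false calls among 134. For the difference between sexes in head, 2% were recovered at 0.5, 34% at 1, 80% at 2 and 96% at 3, with 5 false calls among 111. The simulated noise was independent between arrays, with the same SD in every group for a given transcript. Real male heads spread more than the other groups, so these rates may not hold for comparisons that use them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.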

Results

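The study compared the lol (Lobe-less) mutant of Drosophila with the w1118 control strain. Its title names Lobe-less as a long noncoding RNA that acts in the development of the mushroom body, the paired brain centre for olfactory learning. Expression of 13873 transcripts was measured in heads and whole bodies of both sexes, with 3 arrays in each of 8 groups. The median SD between replicates lay between 0.164 and 0.255 log2, and was highest in w1118 male heads. Replicate arrays correlated at 0.912 to 0.97 in w1118 male heads and 0.933 to 0.986 in lol male heads, across transcripts, and at 0.974 or more in the other 6 groups.

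A group of 162 transcripts differed between lol and w1118 in the same direction in all 4 genotype comparisons. Of these, 88 were higher and 74 lower in lol, where independent lists would give 0.0047 and 0.0073. The lists are not independent, since they share the strains and the spread estimated per transcript, so these figures are a reference only. In each of the 4 comparisons, 37 of the higher and 31 of the lower ones differed by at least 1 log2. FBtr0076832 was higher in lol by 3.23 ± 0.26 (SE) log2 in female heads, 4.07 in female bodies, 3.67 in male heads and 4.09 in male bodies, with a largest adjusted p of 1.87e-07 (limma). FBtr0084918 was higher by 3.04 to 3.77 log2. FBtr0087457 was lower, at -3.67 ± 0.23 (SE) in female heads and -4.31 in male bodies, and FBtr0083920 at -3.67 ± 0.41 and -4.75. In male heads FBtr0083920 lost its call with the 6 compared arrays alone (adjusted p = 0.0685). At least 1 genotype comparison called 1896 transcripts, of which 1258 were called in exactly 1 and 9 were called in opposite directions in different comparisons. Across transcripts, which are not independent replicates, the log2 differences of pairs of comparisons correlated at 0.38 to 0.6. The count of 162 was 105 with the arrays of one tissue or sex in the fit, 33 with the compared groups alone, 321 with array weights and 96 without 4 head arrays described below. Of the 96, 87 were among the 162.

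**Figure D1:**
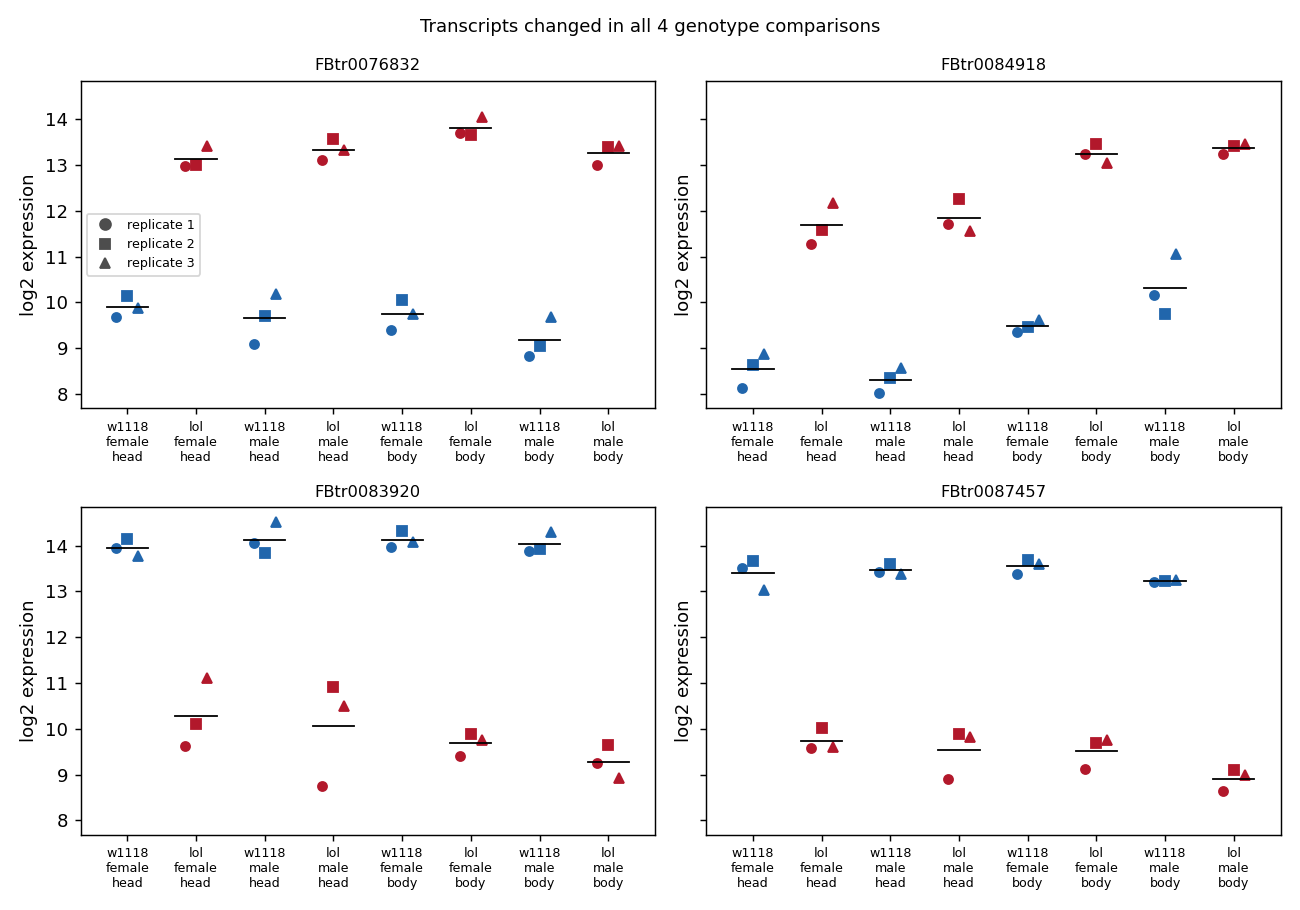
Log2 expression (vertical axis) of 4 transcripts changed in all 4 genotype comparisons, by group (horizontal axis). Points are single arrays with the replicate number as symbol, blue for w1118 and red for lol, and lines are means of 3 arrays. FBtr0076832 and FBtr0084918 lie higher and FBtr0083920 and FBtr0087457 lower on every lol array than on the w1118 arrays of the same sex and tissue.

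In female heads, LanA, a laminin alpha chain of basement membranes, fell in lol from 14.35 ± 0.27 to 13.48 ± 0.12 (SD, n = 3), a log2 difference of -0.87 (adjusted p = 0.000595, limma). SuUR, which restrains replication of heterochromatin in polytene chromosomes, fell by 0.76 (adjusted p = 0.0323). Among the 16 named transcripts, 0 rose, 2 fell and 14 did not pass, and 2 also passed when adjusted over the list alone. Of all transcripts, 503 changed, 264 higher and 239 lower in lol, and 220 of them by at least 1 log2 (115 higher and 105 lower). FBtr0087949 rose from 8.76 ± 0.39 to 13.13 ± 0.28 and FBtr0070490 from 8.66 ± 0.76 to 12.59 ± 0.15. FBtr0078518 fell from 14.68 ± 0.27 to 9.02 ± 0.39, 50.4-fold, and FBtr0082659 fell 20.35-fold. Transcripts of the body-enriched, sex-neutral set stood 0.4 log2 higher in lol female heads (median, 15 rose and 1 fell of 214, camera adjusted p = 1.3e-06, and adjusted p = 0.86 with an estimated correlation). This rested on 1 array, since the median was 0.07 without lol female head replicate 1 (camera adjusted p = 0.27). The count of 503 was 242 with head arrays alone in the fit, 171 with the 6 compared arrays, 1012 with array weights and 304 without w1118 female head replicate 2. SuUR lost its call with head arrays alone, with the 6 compared arrays, without the 4 head arrays described below, and without w1118 replicate 2 or 3 or lol replicate 1 or 3 (adjusted p between 0.0774 and 0.205). LanA lost it with the 6 compared arrays (adjusted p = 0.0802).

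In male heads, LanA also fell in lol, from 14.11 ± 0.25 to 13.47 ± 0.08 (SD, n = 3), a log2 difference of -0.64 (adjusted p = 0.00728, limma). It was the only one of the 16 named transcripts called, with 0 higher and 15 not past the threshold, and 1 was called when adjusted over the list alone. Of all transcripts, 649 changed, 329 higher and 320 lower, and 290 by at least 1 log2 (154 higher and 136 lower). Falls outnumbered rises with any single male head array left out, as without w1118 replicate 3 (514 higher, 754 lower) or lol replicate 2 (178 and 270). FBtr0070490 rose from 8.71 ± 1.07 to 12.99 ± 0.06 and FBtr0082376 from 9.29 ± 0.52 to 13.11 ± 0.27. FBtr0078518 fell from 15.06 ± 0.09, near the top of the scale, to 9.52 ± 0.26, 46.72-fold, and FBtr0082659 fell 28.87-fold. Both of these falls were thus seen in heads of either sex.

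Male-body-biased transcripts had a median difference of -0.53 log2 in lol male heads (10 rose, 17 fell and 1412 did not pass, camera adjusted p = 2.3e-13, and adjusted p = 0.6 with an estimated correlation). The body-enriched, sex-neutral set had a median of -0.48 (5 rose and 7 fell of 214, camera adjusted p = 8.2e-05, and adjusted p = 0.6 with an estimated correlation). The median level of the male-body-biased set was 9.88 on w1118 male head replicate 1, 10.67 on replicate 2 and 10.16 on lol replicate 1, against 8.4 to 8.48 on the other 3 male head arrays. The sex-neutral set stood at 10.62, 10.93 and 10.58 on the same 3 arrays and at 10.37 on lol female head replicate 1. On the other 8 head arrays it lay between 8.68 and 9.11. Without these 4 arrays, which were picked by the levels of these sets, so that a median near 0 follows from the choice, and which leaves w1118 male heads with 1 array that is assumed to vary like the other groups, the median difference was 0.08 for the male-body-biased and 0.1 for the sex-neutral set, and 225 transcripts were called, 198 of them among the 649. LanA stayed called without the 4 arrays (-0.94, adjusted p = 0.02). Without w1118 male head replicate 2 alone, the medians were -0.1 (camera adjusted p = 0.37) and -0.23 (0.21), and the sex-neutral set also missed the threshold without w1118 replicate 1 (-0.31, 0.065) or lol replicate 3 (-0.25, 0.13). Without w1118 replicate 3 the medians were -1.03 and -0.92, and without lol replicate 1 they were -0.96 and -0.98. The count of 649 was 309 with head arrays alone, 59 with the 6 compared arrays and 2290 with array weights, 401 and 1268 without w1118 male head replicates 2 and 3, and 1079 and 385 without lol replicates 1 and 3. LanA was not called with head arrays alone (adjusted p = 0.0897) or the 6 compared arrays (0.244).

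**Figure D2:**
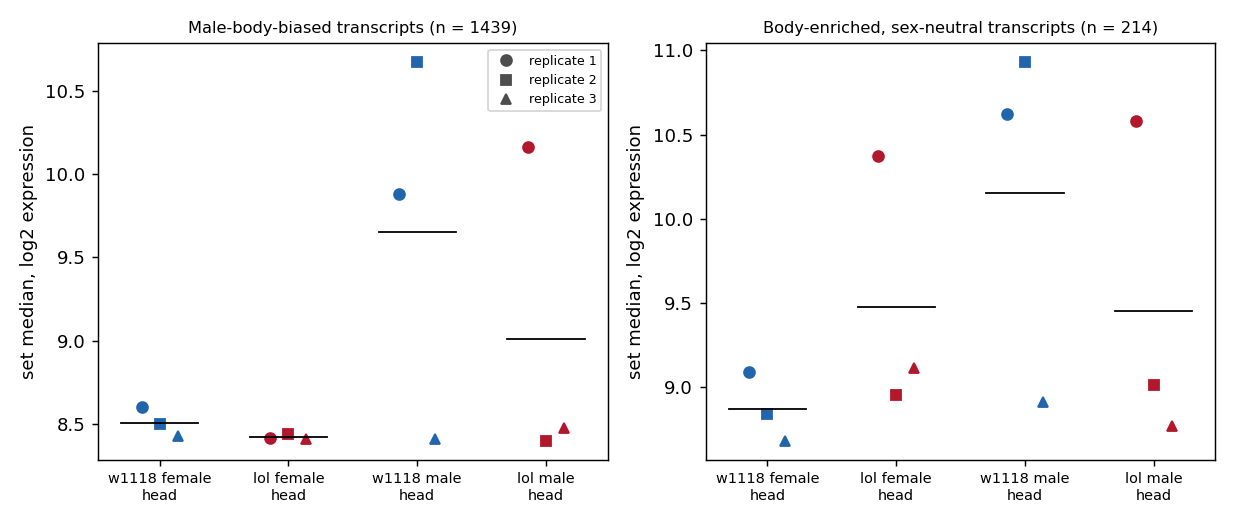
Median log2 expression (vertical axis) of male-body-biased (left) and body-enriched, sex-neutral transcripts (right) on each head array, by group (horizontal axis). Points are single arrays with the replicate number as symbol, blue for w1118 and red for lol, and lines are means of 3 arrays. The male arrays at 9.88, 10.67 and 10.16 on the left also stand out on the right, with lol female head replicate 1 at 10.37.

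In female whole bodies, transcripts that w1118 females express more than males by at least 2 log2 were lower in lol. Of these 180 female-body-biased transcripts, 76 fell, 0 rose and 104 did not pass, with a median of -1.14 log2 (camera adjusted p = 3.1e-50, and adjusted p = 0.013 with an estimated correlation). Their median level was 11.68, 10.98 and 11.98 on the 3 w1118 arrays and 10.27, 10.49 and 10.63 on the 3 lol arrays. The set was defined on the same w1118 arrays. When it was defined from a single w1118 female array and compared with the other pair, the median was -0.72, -1.04 and -0.6 log2. Defined on the lol groups instead, the set held 116 transcripts with a median of -0.23, and 68.1% of them lay below 0, against 94.4% of the 180. Head-enriched transcripts, as defined in males, had a median of 0.21 (47 rose and 5 fell of 493, camera adjusted p = 5.3e-11, adjusted p = 0.17 with an estimated correlation, and fry adjusted p = 0.024). The body-enriched set of females held 17 that rose and 85 that fell of 586, with a median of -0.02 and a mean of -0.28 (adjusted p = 0.46 with an estimated correlation).

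**Figure D3:**
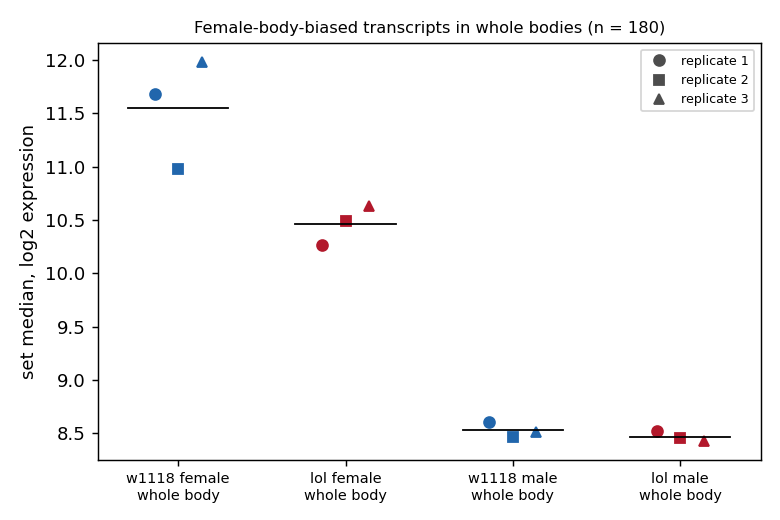
Median log2 expression (vertical axis) of the 180 female-body-biased transcripts on each whole body array, by group (horizontal axis). Points are single arrays with the replicate number as symbol, blue for w1118 and red for lol, and lines are means of 3 arrays. The lol female arrays lie between 10.27 and 10.63, below the w1118 female arrays, and male arrays lie at 8.61 or lower.

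Among the named transcripts, SuUR fell in lol female bodies from 13.48 ± 0.12 to 12.76 ± 0.02 (SD, n = 3), a log2 difference of -0.73 (adjusted p = 0.0346, limma). The transcript of sle (slender lobes) fell from 13.8 ± 0.22 to 13.12 ± 0.17, by 0.68 (adjusted p = 0.0306). LanA did not pass at -0.45 (adjusted p = 0.0606), though it did with an intensity trend (0.0421), with body arrays alone (0.0366) and with array weights (0.0182). Thus 0 of 16 rose, 2 fell and 14 did not pass, and 4 passed when adjusted over the list alone. Of all transcripts, 676 changed, 357 higher and 319 lower, and 310 by at least 1 log2 (132 higher and 178 lower). Without w1118 female whole body replicate 2 the balance of calls turned, with 295 higher and 386 lower, and also without lol replicate 3 (186 and 204). FBtr0087956 rose from 8.67 ± 0.22 to 12.83 ± 0.04 and FBtr0075181 from 9.93 ± 0.24 to 14.01 ± 0.32. FBtr0089323 fell from 12.52 ± 0.26 to 7.73 ± 0.23, 27.65-fold, and FBtr0078518 fell 24.94-fold. The count of 676 was 1346 with array weights, 356 and 424 without w1118 replicates 1 and 3, and 442, 447 and 390 without lol replicates 1, 2 and 3. SuUR lost its call without w1118 replicate 1 or 3 or any lol replicate (adjusted p between 0.0923 and 0.131), and sle without w1118 replicate 1 or 3, lol replicate 1 or 3, or with the 6 compared arrays alone (between 0.0699 and 0.15).

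In male whole bodies, 401 transcripts were higher and 799 lower in lol, of 1200 called. Of the 376 that differed by at least 1 log2, 184 were higher and 192 lower, so the excess of falls lay in the smaller differences. LanA fell from 14.29 ± 0.09 to 13.7 ± 0.16 (SD, n = 3), a log2 difference of -0.59 (adjusted p = 0.00969, limma). It was the only call among the 16 named transcripts, with 15 not past the threshold, and 1 passed when adjusted over the list alone (with array weights 1 was higher and 8 were lower). FBtr0086596 rose from 7.96 ± 0.13 to 12.07 ± 0.16 and FBtr0076832 from 9.18 ± 0.43 to 13.27 ± 0.22. FBtr0083920 fell from 14.03 ± 0.22 to 9.28 ± 0.36, 26.93-fold, and FBtr0077977 fell from 12.29 ± 0.16 to 7.82 ± 0.22. Male-body-biased transcripts had a median of 0.35 log2 (57 rose and 12 fell of 1439, camera adjusted p = 3.7e-11, and adjusted p = 0.95 with an estimated correlation). The count of 1200 was 782 with the 6 compared arrays (377 higher and 405 lower), 5115 with array weights, 705 and 612 without w1118 replicates 1 and 2, and 714 and 779 without lol replicates 1 and 2. LanA just missed the threshold with the 6 compared arrays (adjusted p = 0.0552) and without replicate 1 of w1118 (0.051) or of lol (0.0532).

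Whether the genotype effect differs between the sexes was tested as an interaction. In heads 0 transcripts passed (limma), and 251 had an unadjusted p under 0.05. Over all transcripts, 3 passed with array weights and 17 without w1118 male head replicate 3. None of the 16 named transcripts passed in any of the interaction tests. In whole bodies 35 passed, 10 with a more positive and 25 with a more negative effect in females. FBtr0077977 differed by 4.42 ± 0.47 (SE) log2 (adjusted p = 0.000117), being at 12.29 in w1118 male bodies and at or below 8.36 in the other body groups. FBtr0085034 differed by 3.15, at a log2 difference of -3.14 in males and 0 in females, where both strains stood at 7.71. FBtr0086596 differed by -3.3 ± 0.25 (adjusted p = 1.09e-06), since it rose by 4.11 in males and 0.81 in females. FBtr0076984 differed by -3.15 (adjusted p = 0.0204) and stood at -2.66 in females, with w1118 males at 7.79. For FBtr0077977, FBtr0085034 and FBtr0076984, the level in the w1118 sex without a fall was near the bottom of the scale, so only a small one could appear there. The call of FBtr0076984 was lost with body arrays alone (0.0775) and without any one of 6 arrays (w1118 female replicate 1, w1118 male 1 and 2, lol female 3, lol male 1 and 2; between 0.0514 and 0.0796). The female-body-biased set differed by -1.2 log2 between the sexes (11 more negative in females, camera adjusted p = 8.7e-45, and adjusted p = 0.021 with an estimated correlation). The set was chosen as low in w1118 males, at 8.43 to 8.61 on male body arrays, so it had little room to fall there, and the difference restates the shift of -1.14 in females. The count of 35 was 51 with quantile normalization again, 28 more positive and 23 more negative, 9 with the lowest 25% of transcripts by mean dropped, 62 with the replicate number as a block (18 more positive and 44 more negative) and 1318 with array weights. It lay between 10 and 21 without any one of the other 10 body arrays, at 119 without w1118 female replicate 2 and at 70 without w1118 male replicate 3.

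Whether it differs between head and whole body was tested in each sex. In females 52 transcripts passed, 32 with a more positive and 20 with a more negative effect in heads. FBtr0089323 differed by 5.03 ± 0.38 (SE) log2 (adjusted p = 8.68e-07, limma), because its fall in bodies had no counterpart in female heads. There both strains lay near the bottom of the scale (7.47 and 7.71), with little room for a fall. FBtr0085861, at 8.1 in w1118 female heads and so likewise with little room to fall, differed by 3.29 (adjusted p = 0.0464). Its call was lost without any single one of the 12 female arrays (between 0.058 and 0.156). It was also lost with quantile normalization again, centring, the replicate block or the lowest 25% dropped. FBtr0075181 differed by -5.18 ± 0.61 (adjusted p = 0.000151), as its rise in bodies was not seen in heads. FBtr0082659 differed by -3.77, with its fall called in female heads and not in female bodies (-0.58, adjusted p = 0.293). The female-body-biased set differed by 0.94 (15 of 180 more positive in heads, adjusted p = 0.011 with an estimated correlation), with medians of 9.06 to 9.28 on w1118 female head arrays, which also left it little room to fall there. The count of 52 was 27 with quantile normalization again, 10 more positive and 17 more negative, 15 with the lowest 25% dropped and 108 with array weights. It lay between 19 and 34 without any one of 10 arrays, at 107 without w1118 female whole body replicate 2 and at 36 without lol female head replicate 3.

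In males 60 transcripts had a genotype effect that differed between head and body, 34 more positive and 26 more negative in heads. FBtr0076388 differed by 3.36 ± 0.35 (SE) log2 (adjusted p = 7.26e-05, limma) and stood at -3.17 in bodies. Male heads stood at 7.67 in w1118 and 7.87 in lol, with little room for a fall. FBtr0089323 differed by 3.26. It fell less in male heads, from 8.65 to 7.47 (-1.19, adjusted p = 0.0111), than in male bodies (-4.44). FBtr0078518 differed by -3.22 ± 0.31 (adjusted p = 2.49e-05), at -5.55 in heads and -2.32 in bodies, and FBtr0082659 by -3.11. The count of 60 was 23 with male arrays alone, 30 with the lowest 25% dropped and 1763 with array weights. It lay between 29 and 39 without any one of 7 arrays (w1118 body replicates 1 and 2, the 3 lol bodies, w1118 head replicate 2, lol head replicate 3) and at 118 without lol male head replicate 1, and it was 45 without the 4 head arrays, 25 of them among the 60.

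In w1118 whole bodies, 6290 transcripts differed between the sexes, 4142 higher in females and 2148 higher in males. Differences of at least 1 log2 were found for 1198 transcripts higher in females and 1785 higher in males. The median over all transcripts was 0.26 toward females as deposited and when centred, and 0.27 with quantile normalization again. CG31178 was the named transcript with the largest difference, at 13.56 ± 0.12 in males and 8.61 ± 0.44 in females (SD, n = 3), 31.08-fold (adjusted p = 1.97e-05, limma). Wdr24, a subunit of the GATOR2 complex upstream of TOR, was higher in females by 0.99, LanA by 0.62, and the histone deacetylase HDAC3 by 0.63. Of the 16 named transcripts, 9 were higher in females, 1 was higher in males and 6 did not pass. The 9 were 7 with the 6 compared arrays alone, where mio (adjusted p = 0.121) and rdx (0.0553) lost their calls. SuUR lost its call without w1118 male replicate 2 (0.0502), and mio also did in several other runs. FBtr0081954 and FBtr0077804 were higher in females by 6.87 and 6.4 log2, and FBtr0085944 and FBtr0079624 were lower by -6.48 and -6.12. In the lol strain, 6015 were higher in females and 2240 in males. Of those higher in males by 2 log2, 1412 were shared by 1439 in w1118 and 1540 in lol, and of those higher in females, 60 were shared by 180 and 116.

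In w1118 heads, 12 transcripts differed between the sexes, 6 in each direction, and 0 of the 16 named ones (CG31178 was called without w1118 male head replicate 3, at -2.54, adjusted p = 0.014). FBtr0081759 was higher in males, at 12.5 ± 0.23 against 10.45 ± 0.17 (SD, n = 3, adjusted p = 0.000361, limma), and it was at male levels in lol male heads as well (12.51). FBtr0079782 was higher in females by 0.94 (adjusted p = 0.000361). FBtr0085531 was higher in females by 1.78 and FBtr0089644 lower by -2.14, both with an adjusted p of 0.0171. Without the 4 head arrays, which leaves 1 w1118 male head array, FBtr0085531 lost its call at an unmoved difference (1.79, adjusted p = 0.436), while FBtr0089644 went to -1 (0.163). FBtr0085531 also lost its call without female replicate 1 or 2 or male replicate 1 or 2, and FBtr0089644 without any female replicate or male replicate 1 or 2. The count of 12 was 1 with head arrays alone, 0 with the 6 compared arrays, 21 with quantile normalization again (13 higher and 8 lower in females), 18 with centring (11 and 7) and 1013 with array weights. It was 7 without any one of the 3 w1118 female heads, 4 without male head replicate 1 and 1182 without male head replicate 3, and 10 without the 4 arrays, 4 of them among the 12.

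Head and whole body of w1118 differed in 5321 transcripts in females, 2727 higher and 2594 lower in heads, and in 7640 in males, 4384 higher and 3256 lower. The named transcript fend was higher in heads by 1.3 in females and 2.02 in males, and NaPi-III, a phosphate transporter, by 0.78 and 1.37. The transcript of sle was lower in heads by -1.47 and -1.41 (adjusted p = 1.64e-06 and 2.33e-06, limma). LanA was lower in female heads (-0.57, adjusted p = 0.00233), and in males it did not pass (-0.18). In females 3 of the 16 were higher and 2 lower in heads, and in males 9 and 2. The median over all transcripts was 0.16 toward heads in males as deposited, and 0.2 with quantile normalization again or centring. In females it was 0 as deposited and 0.06 with either. Small differences toward male heads were not told apart from this shift. The 9 were 5 with the 6 compared arrays alone, where alpha-Spec, mio, CG16974 and rdx lost their calls, and 5 without the 4 head arrays, where alpha-Spec, mio, kis and rdx did. In females the 3 were 5 with centring, and 2 wherever CG16974 lost its call, as with the 6 compared arrays. FBtr0085503 and FBtr0087024 were higher in female heads by 3.03 and 2.92 log2, and FBtr0084128 and FBtr0086808 lower by -7.75 ± 1.42 and -7.45 ± 1.38 (SE). Their levels in female bodies, 15.33 and 15.59, lie near the top of the scale, where differences are compressed. In males FBtr0088503 and FBtr0074126 were higher by 3.46 and 3.33, and FBtr0087854 and FBtr0079701 lower by -6.53 and -6.01. Of transcripts higher in heads by 2 log2, 280 were found in females and 493 in males, and 238 in both.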

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

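The tests of splits were planned before the data were examined, and the tests on transcript sets, on single head arrays and on splits by pairs were chosen after the results had been seen. Results stand here because a genotype effect differed between sexes or between tissues in a test of that difference. Groups of 3 arrays are too small for a test of outlying samples.

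Between the sexes in whole body, 35 transcripts differed, led by FBtr0077977 (4.42 log2), FBtr0085034 (3.15), FBtr0086596 (-3.3) and FBtr0076984 (-3.15). After the genotype effect common to both sexes was taken off, 1 of 100 drawn splits of the arrays (the real one) gave as many. The highest other gave 9. The rest of the effect in each sex stayed in these splits and added to their spread, so the 9 does not measure what chance alone gives. The rank of the real split argues only against the absence of any difference between the sexes. It does not tell how many of the 35 are due to chance. The 9 came from the 39 splits that part all 3 same-numbered pairs of male bodies, as the real one does, and the others gave at most 2. Between tissues in females, 52 differed, with FBtr0089323 (5.03), FBtr0085861 (3.29), FBtr0075181 (-5.18) and FBtr0082659 (-3.77) in front. Again 1 of 100 splits gave as many, and the highest other gave 1. Between tissues in males, 60 differed, with FBtr0076388 (3.36), FBtr0089323 (3.26), FBtr0078518 (-3.22) and FBtr0082659 (-3.11). Here 9 of 100 splits gave as many and the highest other 1542, so chance is not excluded for that count, and among the 43 that part every male body pair the highest other gave 1320. The split at 1542 points to a structure among the male arrays. For the sex difference of the effect in heads, with 0 calls, all 100 splits must give as many, so the count says nothing about chance, and the highest other gave 2528, which points to a structure among the head arrays.

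With 3 arrays against 3 there are 10 splits, which are too few for a share under 0.05. The real split called 503 transcripts in female heads and 676 in female bodies, and the highest other called 1 in each. It called 1200 in male bodies (highest other 0, whether or not every pair was parted), 6290 between the sexes in w1118 bodies (4), 5321 between tissues in females (0) and 7640 in males (1). In male heads 2 of the 10 splits called as many as the real 649, and the other called 2588. It set w1118 replicates 1 and 2 and lol replicate 1 against the rest, which points to a structure among these arrays. For the sexes in w1118 heads the real split called 12 and another called 15. That one set female replicate 1 with male replicates 1 and 2. For the transcripts changed in all 4 genotype comparisons, 1 of 100 drawn splits (the real one) gave 162 and the highest other gave 0. The strain difference stayed in these splits and added to their spread, which makes calls in all 4 comparisons unlikely there. The 0 therefore does not measure what chance alone gives. The rank of the real split argues only against the absence of any strain difference. It does not tell how many of the 162 are due to chance. The splits also cannot tell the lol genotype from other differences between the strains.

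The first pattern is the raised level of body-enriched transcripts on 4 head arrays (w1118 male replicates 1 and 2, lol male replicate 1, lol female replicate 1). Whole body arrays labelled as heads are argued against by the head-enriched set of females, whose lowest median on the 4 arrays was 12.53, while the highest on a body array was 10.77. A lower level in lol through the genotype cannot be told apart for the male-body-biased set, since 3 arrays against 3 are too few and raised arrays occur in both strains (log2 difference -0.64, exact two-sided permutation p = 0.6, smallest possible 0.1). Carry-over of body parts through the sieve may explain the pattern: on the scale of intensity, the sex-neutral set gave body shares of 10%, 14% and 12% on the 3 male arrays, and the male-body-biased set, which shares no transcript with it, gave 9.3%, 20% and 9.6%, within a factor of 1.4. The share was 5.8% on the female array. These arrays were picked by the levels of the same sets, so raised shares from both follow from the choice. For w1118 males the only head array left as the reference was replicate 3. The likeness of the shares is therefore weak support.

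The second pattern is the lower female-body-biased set in lol female bodies, which differed by -1.2 between the sexes and by 0.94 between tissues, though its low levels in male bodies (8.43 to 8.61) and female heads (9.06 to 9.28 in w1118) left little room for a fall there, so neither shows an effect specific to female bodies. Selection of the set on the arrays it was compared with is argued against as the whole cause, since sets from a single control array kept medians of -0.6 or lower against the other pair, but a set defined on the lol groups, where selection acts the opposite way, had a median of -0.23, so the size of the shift stays open. Whether the authors' normalization had a part cannot be told from transcripts outside the set at the same w1118 female body level. Their median was 0.01, with an SD of 0.065 over the 3 lol arrays. Quantile normalization between arrays tends to hold a typical difference near 0, so this value cannot decide the question. It shows only that the set fell relative to other transcripts of the same level. A smaller share of female-specific tissue in the RNA may explain the lower set but cannot be told apart from lower expression within that tissue. The head-enriched set defined in males had a median of 0.21, whose camera call was lost with an estimated correlation (adjusted p = 0.17), while fry called it (adjusted p = 0.024). The sex-neutral set had a median of 0.11 (camera adjusted p = 0.48, adjusted p = 0.89 with an estimated correlation, fry adjusted p = 0.81). An effect of the genotype, or of the separate cultures, on the female-biased transcripts stays open and untested, and the w1118 arrays themselves spread from 10.98 to 11.98.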

How the results depend on the processing

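The alternatives were planned, except the fit without 4 head arrays and all runs on transcript sets, which were chosen after the data had been seen. The fit with a single transcript per gene and the gene list tests were not run, since they need gene names. The trend with a robust prior and median centring moved no total of called transcripts by over 1.5 times. With centring, the named transcripts higher in w1118 female heads than bodies went from 3 to 5. The transcripts higher in w1118 female than male heads went from 6 to 11. The cause of the changes below was not tested, except where fewer arrays or fewer transcripts are part of the alternative.

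With the arrays of one tissue or sex, the counts were 242 (genotype effect in female head, 503 before), 309 (male head, 649), 23 (genotype by tissue in male, 60), 1 (sex difference in w1118 head, 12) and 105 (all 4 genotype comparisons, 162). With the compared groups alone they were 171 in female head, 59 in male head, 782 in male whole body (1200), 23 for tissue in male, 0 for sex in head and 33 for all 4. Quantile normalization again gave 27 for genotype by tissue in female (52) and 21 for sex in head. Dropping the lowest 25% by mean gave 9 for genotype by sex in whole body (35), 15 for tissue in female and 30 for tissue in male. Array weights gave 1012, 1346, 2290 and 5115 for the genotype effect in female head, female body (676), male head and male body, 3, 1318, 108 and 1763 for the interactions by sex in head (0) and body and by tissue in female and male, 1013 for sex in head and 321 for all 4. The weights had not converged, and 1 array, w1118 male whole body replicate 1, had a weight of 22.03. Without the 4 head arrays 225 were called in male head and 96 in all 4, and the medians of the male-body-biased and the sex-neutral set in male heads turned from -0.53 to 0.08 and from -0.48 to 0.1, which follows from the choice of these arrays by the levels of the same sets.

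The replicate block gave 62 for genotype by sex in whole body, where 35 were called, and changed no other total by over 1.5 times. For the sex difference in w1118 heads it gave 11 higher and 7 lower in females, against 6 in each direction before. Among the named and printed transcripts and the sets it changed the call of FBtr0085861 alone (genotype by tissue in female, adjusted p = 0.0583). Same-numbered arrays correlated at 0.46, 0.12 and -0.11 in female heads, 0.4, 0.085 and 0.51 in female bodies and 0.59, -0.59 and 0.67 in male heads. In none of these did every array correlate best with its own number, whereas in male bodies each did, and the block gave 1321 there.

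Leaving out 1 array at a time gave 304 to 473 in female head, 356 to 681 in female body, 385 to 1268 in male head and 612 to 1617 in male body. The ranges were 0 to 17 and 10 to 119 for genotype by sex in head and body, and 19 to 107 and 29 to 118 for genotype by tissue in female and male. They were 4 to 1182 and 5434 to 5980 for sex in head and body, 4557 to 4806 and 6685 to 7456 for tissue in females and males, and 126 to 175 for all 4. Over all named and printed transcripts and alternatives, 1261 called values kept direction and call, 98 lost their call with the same direction, and none changed direction. The trend, the fits to fewer groups, the dropped transcripts and the block leave a log2 difference as it was, so no direction could change there. The printed transcripts were also picked for large differences, which makes a kept direction likely. Of the values not called, 23 gained a call with the same direction and 1365 did not, 89 of which changed sign. Of the set values, 83 kept both, 11 lost their call and 2 changed direction. Levels near the bottom of the scale limit how large a fall can appear, and levels over 15 how large a rise.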

Other observations

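The tests in this part were chosen after the results had been seen. A pair of transcripts that female bodies express strongly, FBtr0071419 (15.74) and FBtr0071424 (15.65), stood at 14.55 and 14.65 on w1118 male whole body replicate 3, and at or below 9.63 on replicates 1 and 2. Their excess on that array over the other pair, 6.25 and 5.12 log2, ranked 1 and 2 among all transcripts. FBtr0077804, also strong in females, was at 8.66 there, the highest of the 6 male bodies, with an excess of 1.23 (rank 20). The median of the female-body-biased set was 8.51, within the range of the other male bodies. FBtr0071419 and FBtr0071424 also varied among male heads, from 9.26 to 14.62 and from 10.88 to 14.01.

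The transcripts changed in all 4 genotype comparisons were unevenly spread over the FlyBase ID numbers, of which those from 70000 up to 90000 were compared, with 13 of 3449 (0.38%) below 75000 and 147 of 9974 (1.5%) from there on. An even spread is argued against by a permutation test of counts per 1000 ID numbers, with called IDs within 5 of each other counted once (p = 0.0006, 10000 permutations). That test asks about unevenness anywhere over these numbers, not about the cut at 75000, which was set after the values had been seen. A loss of calls for every comparison below 75000 is argued against too, since 55.9% of its transcripts were called in the male tissue difference of w1118, against 55.1% above. At least 1 genotype comparison called 10.2% below 75000 and 15% above, so a loss of genotype calls in general is not argued against. A candidate explanation is a difference in strain background over some stretches of the genome, if ID numbers follow map position, and it was not tested. Of the 9 reference matches below 75000, 3 lie on the X chromosome and 6 elsewhere, and 0 of 34 above lie on X, so the numbers were not turned into chromosomes.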
